A study of Rattus norvegicus with 3 samples.

How the data were processed

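Small RNA of primary hepatic stellate cells from 3 Wistar rats was measured on a microarray of microRNA (miRNA) probes. Per the labels, each sample record holds the RNA of 1 rat at day 0 in channel 1 and at day 10 of culture in channel 2. The cells were kept in high-glucose DMEM with fetal bovine serum, and RNA was isolated and labelled with commercial miRNA kits, per the labels' protocols. Both dye orders are listed on every record, which holds 1 ratio per probe, so each rat counts as 1 replicate. Whether and how the dye swap was combined before deposit is not given in the sources used here.

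The deposited table has 1434 rows and 1 column of signed log ratios per rat. The log base, the normalization, the centring and the direction of the ratio are not given in the sources used here. The deposited values were read as log2 ratios, because their lowest value of -9.56 would on a base 10 scale exceed the range of a scanner. Natural log is not excluded, and fold sizes depend on this choice. A positive value is called likely day 10 over day 0, from the channel order in the labels, since the dyes do not settle it. The columns' medians over all rows were 0.0496, -0.0181 and -0.0150 in rats 1, 2 and 3, which are also the repeated values described next.

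In each column 1 repeated value filled most rows: 1215 rows in rat 1, 1199 in rat 2 and 1313 in rat 3. Most of the 289 blank spots carried the same value, so it was taken as a placeholder for spots without a measured ratio. This reading was chosen after the values were seen. The rows comprised 1053 probes with a miRNA name, 289 blanks, 76 numbered probes without a name, 10 probes for other small RNAs, 5 dye normalization controls and 1 platform control. Only named miRNA probes with a value other than the placeholder in all 3 rats were tested.

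Smaller groups of spots also carried values identical at full precision within an array. Among named probes with a measured ratio these were 47 of 189 in rat 1, 29 of 214 in rat 2 and 23 of 105 in rat 3. Blank spots carried 5 of the 13 such values of rat 1, 2 of the 12 of rat 2 and 1 of the 7 of rat 3. Such ratios cannot be taken as separate measurements of each probe. They lay between -1.35 and 0.65 on the log2 scale. They stayed in the test, whose rule was written before the data were examined, and 22 of the 90 probes tested had 1 or more. Leaving those probes out was added as an alternative after the values were seen.

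The log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3, as an intercept-only model with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom came out infinite. Every probe was therefore tested with the pooled SD of 1.62 and a standard error of 0.936, and a call depended on the mean ratio alone. The smallest mean size past the threshold was 2.37 and the largest not past it was 2.28. The test treats probes as independent, but 32.6% of the residual sum of squares was a shift common to all probes of a rat, so the p-values are too small. A two-sided exact sign-flip test of a single probe cannot go below p = 0.25 with 3 rats. Simulated data held independent probes with the pooled SD, of which 20 of 90 changed. The model recovered 13.4% of changes of 2 log2 units, 89.9% of changes of 4 and 100% of changes of 8. The mean number of false calls over 50 runs was 0.22, 0.64 and 0.74 in that order. The array's signal intensities were not used here, so the precision rests on the number of rats.

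Lists of miRNAs were fixed before the data were examined: 17 lists of cell types, families and genomic clusters. A miRNA with several probes took the mean of its rat-named probes, or of mouse or human probes where none was rat-named, or else of the other species' probes. The names miR-122a, miR-92, miR-422b and miR-146 were read as the older names of miR-122, miR-92a, miR-378 and miR-146a. This gave 73 miRNAs, counted by name and fitted in the same way. Names that differ stayed apart, as with miR-194 and zebrafish miR-194a, so the number of distinct miRNAs may be smaller. Lists with at least 3 measured miRNAs were tested against the other miRNAs with limma's camera at a preset correlation of 0.01, adjusted over the 7 lists, with an estimated correlation as the alternative. Limma's fry was also run on these lists. It asks another question, whether the members of a list move one way against no change, and compares them with no other miRNAs.

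Named miRNAs followed a rule fixed before the data were examined. They were the 12 highest and the 12 lowest mean ratios among probes past the threshold with 1 sign in all 3 rats, with open places filled by the smallest unadjusted p. Up to 4 members of each list were added: the 2 with the smallest p, then the highest and the lowest mean. Names outside this rule are given as chosen after their values were seen.

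Alternatives were centring each array on its median, scaling to a common median absolute deviation, probe subsets, leaving out each rat, a robust prior, no moderation, a fold filter of 1 log2 unit, an adjusted p under 0.1, probes with values in at least 2 rats, and turning all signs. Scaling divided each centred array by its median absolute deviation relative to the geometric mean, because limma's own scaling cannot be used on centred arrays. Centring on the dye controls or on the placeholder, and keeping the placeholder as a value, were added after the values were seen. Averaging repeated rows by the median was not run, since 0 row names were duplicated.

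No genome build is given in the sources used here, so no coordinates are printed. The RefSeq gene table of assembly GRCr8 was used only to see which miRNA genes neighbour each other. Summaries and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.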

Results

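Hepatic stellate cells are the vitamin A-storing cells of the liver that turn into myofibroblast-like cells on culture plastic. The series title describes the cells as activated in vitro, and the comparison asks which miRNAs differ between day 0 and day 10 within the same animal. The 3 replicates were 3 different rats. Of the 1053 probes with a miRNA name, 189 had a measured ratio in rat 1, 214 in rat 2 and 105 in rat 3. In all 3 rats 90 probes had one, which carried 76 miRNA names, and 789 had none in any rat. The medians of the 90 ratios were -0.62, -0.78 and 0.16 in rats 1, 2 and 3. All ratios are given as log2, likely day 10 over day 0, and neither the base nor the direction is settled by the sources used here.

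The lowest ratios belonged to miR-122, the most abundant miRNA of hepatocytes, and to miR-126, a miRNA of endothelial cells. The ratio of miR-122 was -7.96, -9.56 and -7.83 in the 3 rats, a mean of -8.45 ± 0.97 (SD, n = 3; limma adjusted p = 2.33e-14). The ratio of miR-126 was -7.82, -9.33 and -5.08, a mean of -7.41 ± 2.16 (SD, n = 3; limma adjusted p = 7.00e-12). A zebrafish-named probe for miR-122 gave -8.24. Both miRNAs were likely lower at day 10, and they fell in 3 of 3 rats.

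The highest ratios belonged to miR-143 and miR-214, which are miRNAs of smooth muscle and mesenchymal cells. For miR-143 a zebrafish-named probe gave 3.91 ± 1.49 and the rat-named probe 3.87 ± 2.00 (SD, n = 3; limma adjusted p = 7.32e-04 for both). For miR-214 the ratio was 3.41, 2.53 and 5.49, a mean of 3.81 ± 1.52 (SD, n = 3; limma adjusted p = 7.88e-04). These miRNAs were likely higher at day 10, and as deposited their ratios were positive in 3 of 3 rats. With dye-control centring the rat-named probe of miR-143 was at -0.10 in rat 1.

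In total 22 of the 90 probes passed the threshold, 9 with a positive and 13 with a negative ratio, for 7 and 12 miRNA names. The ratio had the same sign in all 3 rats for 21 of the 22 as deposited, and for 20 with dye-control centring. The other positive names were miR-125b at 3.30, miR-145 at 3.21, miR-221 at 2.95, miR-31 at 2.81 and miR-21 at 2.40. The SDs between rats were 2.59, 1.22, 2.00, 0.48 and 1.81 in that order. The probe for miR-145 that passed was named for zebrafish. The rat-named probe gave a mean of 1.16 and did not pass, although all ratios of both probes were positive as deposited. The other negative names were miR-195 at -3.86, miR-30b at -3.39, miR-30c at -3.28, miR-30d at -3.12, miR-194 at -2.60, miR-192 at -2.60, zebrafish miR-194a at -2.57, miR-30a-5p at -2.42 and miR-26a at -2.37. Their SDs lay between 1.82 and 3.14. In rat 3 the ratios of miR-195, miR-30c and miR-30a-5p were -0.27, -0.83 and -0.10, and each of these values was carried by other probes of that array at full precision. They cannot be taken as separate measurements, and for these 3 miRNAs the sign in rat 3 rests on a shared value. Without the probes that had such a value in any rat, 68 were tested and 19 passed, all of them among those that passed in the full set.

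Among positive ratios that did not pass, let-7b had a mean of 1.89, let-7c 1.83, zebrafish miR-125c 1.77, miR-22 1.54 and miR-199a* 1.47, each positive in 3 of 3 rats as deposited. With each array centred on its median, let-7b, let-7c and miR-125c passed, but without rat 3 the means of let-7b and let-7c were 0.89 and 0.90. The negative ratio nearest to the threshold under the naming rule was human miR-483 at -2.17, which carried the same value as miR-30c in rat 3 and passed with dye-control centring and without rat 3, while its mean was -1.15 without rat 2. The miRNA that passed with mixed signs was miR-146a, a miRNA of inflammatory signalling, with -5.11, -8.17 and 1.06.

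**Figure D1:**
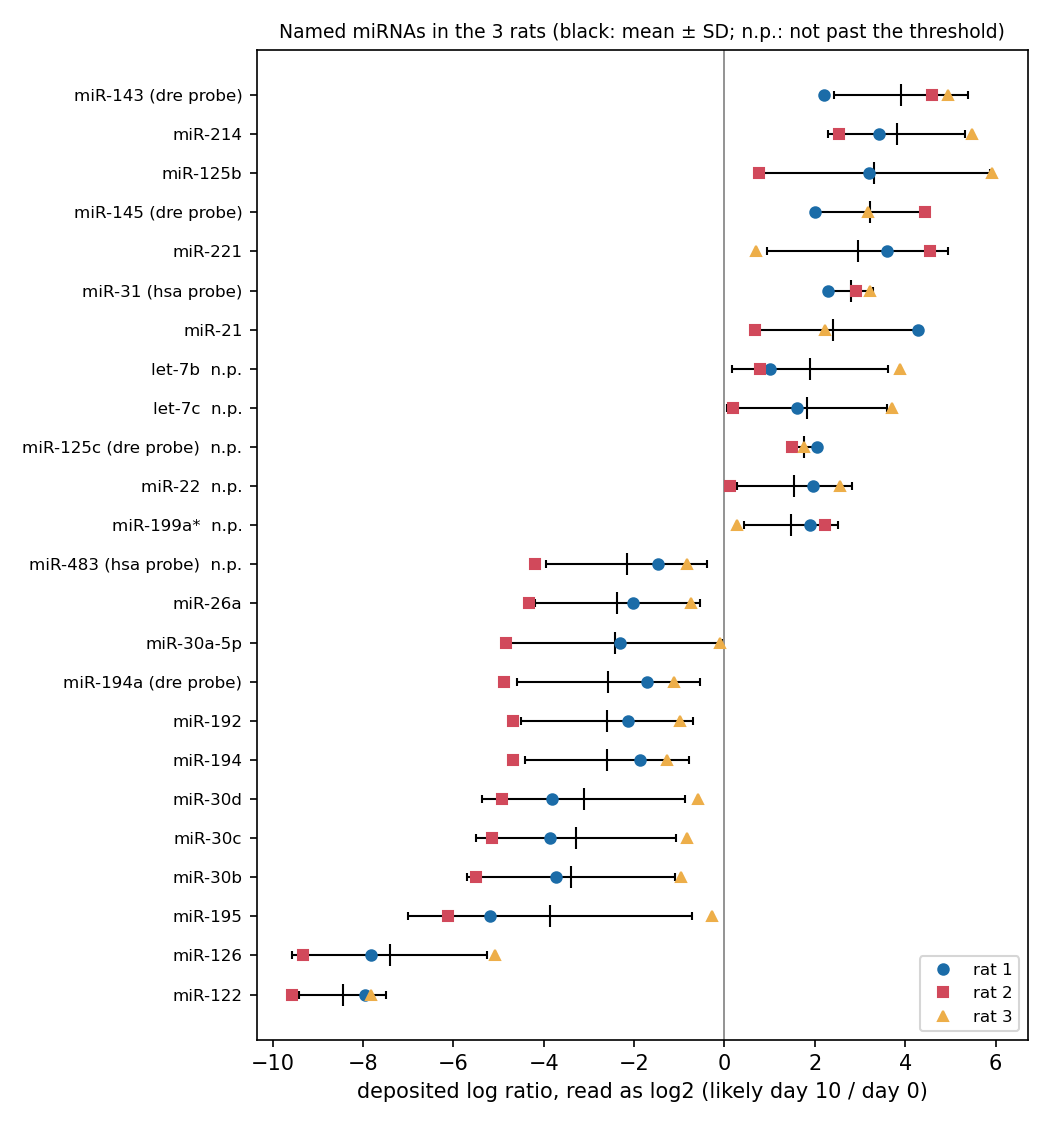
Log2 ratio (x axis, likely day 10 over day 0) of each named miRNA (y axis) in rats 1, 2 and 3 (coloured points), with the mean and SD in black. The points of miR-122 lie between -9.56 and -7.83, and those of miR-143, plotted for its zebrafish-named probe, between 2.21 and 4.94; n.p. marks miRNAs that did not pass the threshold.

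The count depended on single animals and on the variance model. Without rat 1, 5 probes passed (both probes of miR-122, both of miR-143, and miR-126), without rat 2, 8 passed, and without rat 3, 30 passed. Single animals also moved called means by over 1.5 times. Without rat 2 the means were -1.57 for miR-194, -1.56 for miR-192, -1.41 for zebrafish miR-194a, -1.21 for miR-30a-5p and -1.39 for miR-26a. The mean of miR-21 was 1.45 without rat 1 and that of miR-125b 1.98 without rat 3. With no moderation 0 passed in limma, and 10 had an unadjusted p under 0.05, against 29 with moderation. The split of 9 positive and 13 negative became 12 and 11 with each array centred on its median, 10 and 8 with scaling, and 3 and 19 with each array centred on its dye controls, where median centring moved the means up by 0.41 and dye-control centring moved them down by 0.82. The probes past the threshold both as deposited and under these 3 settings numbered 11, for miR-122, miR-126, miR-143, miR-214, miR-195, miR-146a, miR-30b, miR-30c and miR-30d. As background, 25 of 289 blank spots had a value other than the placeholder in some rat and 7 in all 3. The mean ratios of these 7 lay between -0.45 and 0.51. On single arrays such blanks ranged from -1.80 to 0.48 in rat 1, -1.82 to 0.38 in rat 2 and -0.42 to 0.66 in rat 3. Probes named for other species only had a value in all 3 rats in 17 of 340 cases, against 90 of 1053 for all named probes. They include the zebrafish-named probes of miR-122, miR-143 and miR-145, so that count is no background rate. Among tested probes named for the nematode only, means ran from -1.89 for miR-265 to 0.20 for miR-49. The ratios of miR-265 were -3.94, -1.63 and -0.10, the last a shared value.

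Of the 12 listed miRNAs of myofibroblasts and smooth muscle, 11 were matched by name on the array. Names with a star were not matched, so miR-199a*, with 1.90, 2.22 and 0.28, was not counted for miR-199a-3p. The 6 members measured in all 3 rats were each positive in 3 of 3 rats as deposited. With dye-control centring 4 of the 6 were, and miR-143 and miR-145 were at -0.10 and -0.52 in rat 1, whose dye controls averaged 1.74. In the fit of 1 value per miRNA, 4 rose (miR-143, miR-214, miR-221 and miR-31), and 5 passed when adjusted over the list alone. The fifth was miR-21, a miRNA linked to fibrosis, whose adjusted p was 0.0482 among probes and 0.0522 in this fit. Its ratios were 4.29, 0.68 and 2.22. The rat-named value of miR-145 was 1.16 ± 0.57 (SD, n = 3). The list median was 2.81, above the other miRNAs with a camera adjusted p of 1.35e-04 in limma, and with an adjusted p = 0.299 with an estimated correlation, which was -0.180. Limma's fry, which tests the members against no change and not against the other miRNAs, gave an adjusted p of 0.00487. Without rat 1, 1 member passed, and without rat 2 and likewise with dye-control centring 2 passed.

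All 3 hepatocyte miRNAs measured in the 3 rats fell: miR-122, miR-192 and miR-194, and 3 passed when adjusted over the list alone. The list median was -2.60 (camera adjusted p = 0.00295 in limma; adjusted p = 0.610 with an estimated correlation; fry adjusted p = 0.128). Only miR-122 passed without rat 1, without rat 2 and with scaling, and the list median was -1.57 without rat 2. Of the endothelial list and of the leukocyte and Kupffer cell list 1 miRNA each was measured in all 3 rats. The endothelial miR-126 fell, and the leukocyte miR-146a passed with a negative mean but was positive in rat 3, each also when adjusted over the list alone. The leukocyte miR-155, measured in rats 1 and 2 only, was positive in both, with 1.24 and 0.10. The call for miR-146a ended without rat 1, without rat 2 and with a robust prior, and its mean was -2.03 without rat 2 and -6.64 without rat 3. Over the lists of other cell types, 25 of 28 measured values were negative, 1 of them of striated muscle, against 361 of 508 for all named probes. In rat 1 the values of miR-206 (striated muscle, -0.13), miR-215 (hepatocyte, -0.62) and miR-146b (leukocyte, -1.35) were also carried by other probes. They cannot be taken as separate measurements. The erythroid, epithelial and cholangiocyte, striated muscle and neuronal lists had 0 members measured in all 3 rats.

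In the miR-30 family, 4 of 5 members were measured and all were negative in 3 of 3 rats. The members miR-30b, miR-30c and miR-30d fell, and 4 passed when adjusted over the list alone. The list median was -3.20 (camera adjusted p = 0.0253 in limma; adjusted p = 0.706 with an estimated correlation; fry adjusted p = 0.338). Here too the estimated correlation, 0.981, was far above the preset 0.01. Without rat 1 and likewise without rat 2, 0 members passed, and without rat 2 the camera adjusted p was 0.0846. The shared values in rat 3 belonged to miR-30c and miR-30a-5p, and without them 2 members were left, both past the threshold but too few for the list test. Members of this family differ by a few bases, so the values of single members are uncertain.

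In the family of miR-15, miR-16 and miR-195, 1 of 3 measured members fell, miR-195, also when adjusted over the list alone, while miR-15a had a mean of -1.93 and miR-16 was negative in rats 1 and 2 and positive in rat 3. That call ended without rat 1 and without rat 2, 2 members passed without rat 3, and only miR-16 was left without probes that had a shared value. The list median was -1.93 (camera adjusted p = 0.189), and -0.77 without rat 2.

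The let-7 family, which is high in differentiated cells, had 7 members measured and 0 past the threshold as deposited, in the whole fit or when adjusted over the list alone. With each array centred on its median 2 passed in the whole fit, let-7b and let-7c. The highest mean was that of let-7b and the lowest that of let-7f, whose ratios were -1.96, -1.46 and 0.06. The list median of 0.84 (camera adjusted p = 0.121) was 1.26 with median centring and 0.025 with dye-control centring, 1.78 without rat 2 and 0.22 without rat 3. Its members are close in sequence, so the values of single members are uncertain. Among the miR-99, miR-100, miR-125 and miR-10 miRNAs 3 were measured and 1 rose, miR-125b, also when adjusted over the list alone. Its ratios were 3.21, 0.76 and 5.93, while miR-99a had -1.57 and miR-99b 0.07. In this fit the call for miR-125b ended without rat 1, without rat 3 and with dye-control centring. The list median of 0.07 (camera adjusted p = 0.411) turned negative without rat 1, without rat 3 and with that centring.

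The other lists held 0 miRNAs past the threshold, in the whole fit or when adjusted over the list alone. In the miR-23/24/27 clusters 5 were measured (list median -0.20; camera adjusted p = 0.626). The lowest mean was that of miR-27b, with ratios of -1.11, -1.43 and -0.19, the last a value shared by several spots. The highest was that of miR-23a, with 0.48, -0.78 and 2.66. Single members were measured of the miR-29 family, which targets collagen transcripts, and of the miR-17/92 clusters. These were miR-29a with -0.87, -1.64 and 2.09, and miR-106a with 0.32, -1.03 and 0.14. The medians of these 3 lists were positive with median centring and without rat 2. Of the 38 miRNAs of the imprinted Dlk1-Dio3 cluster, miR-341 and miR-377 were measured, with 1.17, 0.23 and 0.48 for the first and 0.53, 0.25 and -1.22 for the second, and their median was negative with dye-control centring and without rat 1. The miR-34 family had 0 members measured in all 3 rats.

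**Figure D2:**
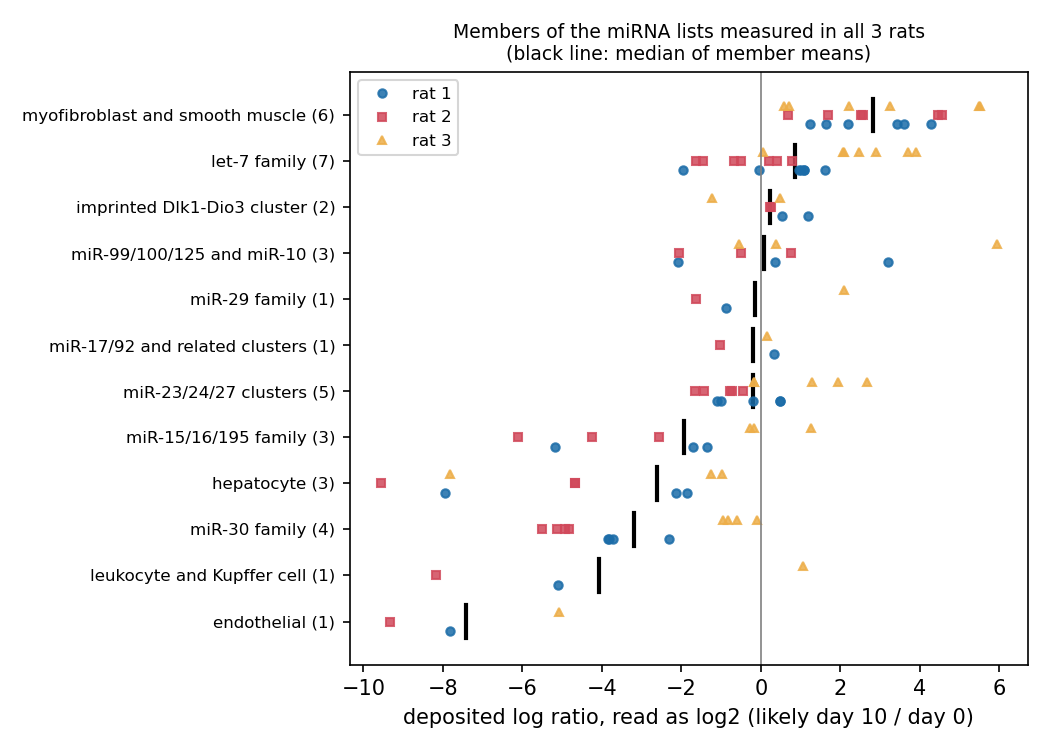
Log2 ratio (x axis, likely day 10 over day 0) in rats 1, 2 and 3 (coloured points) of the members of each list measured in all 3 rats (number in brackets on the y axis), with the median of the member means as a black line. All points of the myofibroblast and smooth muscle list lie above 0 as deposited, where 4 of its 6 members stay positive in every rat with dye-control centring, and those of the hepatocyte and miR-30 lists lie below 0; the medians of the let-7, miR-29, miR-17/92, miR-23/24/27, Dlk1-Dio3 and miR-99 to miR-10 lists lie between -0.20 and 0.84, and those of all these except let-7 change sign with the centring.

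Ratios of the 90 probes were compared between animals across probes, which are not independent replicates. Pearson's r was 0.799 between rats 1 and 2, 0.722 between rats 1 and 3 and 0.640 between rats 2 and 3, with Spearman's rho of 0.704, 0.620 and 0.401. The same sign in all 3 rats was seen for 49 probes, or 54.4%, where independent signs would give 25%. Of the 68 probes without a shared value, 33 had the same sign in all 3 rats. A size of at least 1 log2 unit with 1 sign in every rat was seen for 12 probes, 7 positive and 5 negative.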

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

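All tests in this part were chosen only after the results were seen.

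Several signals lay outside the named miRNAs. The 5 dye normalization controls had mean log2 ratios of 1.74, 0.16 and 0.55 in rats 1, 2 and 3. A value other than the placeholder in all 3 rats was present on 7 blank spots. A numbered probe without a name had a mean ratio of -1.22 ± 1.20 (SD, n = 3), of which the rat 3 value was shared by other spots.

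The miRNAs of hepatocytes, endothelial cells and leukocytes had mostly negative ratios beside the positive myofibroblast list. If RNA of other liver cells was present at day 0 and lost by day 10, nearly all these ratios would be negative. The test took all lists of other cell types, which added 1 negative value of striated muscle. Of its 28 values 3 were positive, or 10.7%, just over the bound of 1 in 10. That share rests in part on negative values also carried by other probes, such as those of miR-206, miR-215 and miR-146b in rat 1. By list, 3 of 13 leukocyte values were positive, against 0 of 11 for hepatocytes and 0 of 3 for endothelial cells. This leaves the explanation open, since no value in these arrays separates loss of other cells from a change within stellate cells. The change of the stellate cells themselves over 10 days, which the design names, stays open as well. Which day carries the extra RNA follows from the direction read for the ratio, and turning it would exchange the days.

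Rat 3 stood apart, with a median of 1.60 above the mean of rats 1 and 2 over the 90 probes. An offset of its whole record may contribute. The spread of rat 3 around the mean of the other rats was compared with the spread between those rats, both put on the scale of 1 rat. Their ratio was 1.21 (95% interval 0.939 to 1.54, from 10000 resamples of probes), which does not decide it. After centring, 16 of 66 probes with 1 sign in rats 1 and 2 had the other sign in rat 3, against 21 of 70 before, and miR-146a was at 0.90 against -4.50 and -7.39, so an offset alone does not account for that probe. A weaker signal of 1 day in rat 3 is also open. That would be day 0 if the ratio is day 10 over day 0, and day 10 if it is turned. Of 51 probes measured in rats 1 and 2 only, 88.2% were negative, against 68.9% of the 90 (Fisher's exact p = 0.0132, two-sided, over probes that are not independent). Some of the 51 carried values shared by several spots, such as miR-100 and miR-424 with -0.38 in rat 1. Shared values of named probes were negative in 45 of 47 cases in rat 1 and 26 of 29 in rat 2. The comparison was not run without them. The rat 3 ratio of miR-122 lay above that of rat 2 by 1.73, near the median shift, but above that of rat 1 by 0.13 only.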

How the results depend on the processing

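Centring on dye controls or placeholder, keeping the placeholder, and leaving out probes with shared values were chosen after the data were seen; the other alternatives were planned.

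Against 22 probes, 14 passed among rat-named probes, 0 without moderation, 2 with values in at least 2 rats (prior degrees of freedom 2.27, both for miR-122) and 0 of 1053 with the placeholder kept, where 15 had an unadjusted p under 0.05. Without 1 rat, 5 to 30 passed. Other alternatives gave 15 to 26, and centring on the median shared 20 of the 22, centring on dye controls 16. Against 14 list members, 0 passed without moderation, 2 with values in at least 2 rats and 3 to 16 without 1 rat. Against 3 shifted lists, 0 were called with an estimated correlation and 2 to 3 without 1 rat. The test of members against no change, fry, called 1 list and is no count of shifted lists. Fewer probes or rats may contribute to the smaller counts, but the sets with more probes, 154 and 1053, also gave fewer calls. Their prior degrees of freedom were 2.27 and 0.96, against infinite in the full fit. The cause of the changes in count was not tested. The list median of miR-99, miR-100, miR-125 and miR-10 of 0.074 lay between -0.074 and 0.36 without 1 rat (-0.065 without rat 1, -0.074 without rat 3), and was -0.56 with values in at least 2 rats and -0.75 with dye-control centring. The mean r between rats of 0.720 was 0.803 over rat-named probes and 0.572 with the placeholder kept. None of the 12 highest and 12 lowest named miRNAs changed sign under any centring, probe set or omission run, apart from turning all signs. Members named only for their lists did, such as miR-29a and miR-106a with median centring and miR-99b with dye-control centring. Signal over background could not be weighed, since intensities were not analysed here.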

Other observations

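All tests in this part were chosen only after the results were seen, and the miRNAs measured in 2 rats were picked after their values were seen.

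Some miRNAs had a measured ratio in rats 1 and 2 and the placeholder in rat 3, so they entered no test. Negative in both were miR-150, a lymphocyte miRNA, with -3.58 and -6.29, miR-26b with -3.35 and -3.43, let-7g with -2.83 and -3.57, and miR-10a with -1.94 and -3.50. Positive in both were miR-199a with 2.38 and 2.53, miR-222 with 1.82 and 1.20, and miR-132 with 1.53 and 0.67, from the myofibroblast list. From outside that list, the leukocyte miR-155 with 1.24 and 0.10 and zebrafish miR-34 with 0.40 and 0.96 were positive in both. The listed miR-34a, miR-34b and miR-34c were at the placeholder in every rat. The hypoxia-linked miR-210 had 0.39 in rat 1 and 2.24 in rat 3.

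Neighbouring miRNA genes had near or far ratios. The difference of miR-194 minus miR-192 was 0.27, 0.01 and -0.29 in the 3 rats, and that of miR-30d minus miR-30b averaged 0.28 ± 0.35 (SD, n = 3). For miR-145 minus miR-143 the gap depended on the probes, with -2.70 ± 2.26 for the rat-named and -0.70 ± 0.92 for the zebrafish-named probes (SD, n = 3). The difference of let-7e minus miR-99b was 1.24 ± 0.73 and positive in 3 of 3 rats, though the rat 3 value of miR-99b was shared by other spots. Those of miR-27a minus miR-23a, at -1.33 ± 1.59, and of miR-27b minus miR-23b, at -0.71 ± 0.87, had no common sign in the 3 rats (SD, n = 3). In rat 3 the values of miR-27a and miR-27b were shared ones as well.

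A further neighbour pair, let-7c and miR-99a, went apart: let-7c minus miR-99a was 3.70, 2.25 and 4.25. Signal of other let-7 members on the let-7c probe may be a cause. In 3 of 3 rats let-7c lay nearer to let-7b than to miR-99a. That test cannot separate shared signal from let-7b and let-7c changing alike, and a difference in processing or decay of the 2 miRNAs was not tested. Only the gene Mirlet7c1 was placed beside that of miR-99a, and let-7c made from any other gene copy was not examined.

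The hypothesis that the deposited ratio is day 10 over day 0 was tested with miRNAs that earlier work reported as higher (7 measured) or lower (5 measured) in activated stellate cells. The median of the first lay above that of the second in 3 of 3 rats, by 3.51, 6.37 and 1.97. Not every member went that way. Of the first, miR-27a and miR-27b were negative in all 3 rats, leaving 5 of 7 positive. In rat 3 both carried the same shared value of -0.19, which is no separate measurement of either. Of the second, miR-16 and miR-29a were positive in rat 3, leaving 3 of 5 negative there. The order of the medians is consistent with the reading that ratios are day 10 over day 0. It rests largely on miRNAs already described above. Of the first, miR-143, miR-214, miR-221, miR-21 and miR-145 also belong to the myofibroblast list. Of the second, miR-122, miR-126 and miR-194 also belong to the hepatocyte or endothelial list, and miR-194 was the median in every rat. The earlier reports may also include the present samples, so the direction stays likely and not settled.

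Exchanging day 0 and day 10 within single rats gave 4 arrangements, counting mirrors once. Only 1 of these, the real one, reached 22 probes, and the highest of the others gave 0. They are too few for a share under 0.05.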
